A study of Homo sapiens with 9 samples.

How the data were processed

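RNA was measured in mesenchymal stromal cells (MSCs) derived from the H1 human embryonic stem cell line, an established line, per the labels. The cells were untreated or had been treated with interferon gamma (IFN-γ), a cytokine of the immune response, for 1 day or for 3 days, with 3 samples per group, which the series design calls biological replicates. Total RNA was amplified and labelled with Cy3 or Cy5 per the labels' protocols, and hybridized to an Agilent array with coding and noncoding RNA probes. The untreated samples carried Cy3, and all samples of both treated groups carried Cy5. Untreated and 1-day samples of the same replicate number shared an array, on a slide that also held the first 3-day sample; the other 3-day samples lay on a slide each. Every comparison with the untreated samples is therefore also a comparison of dyes, with no dye swap, and only the comparison of 3 days with 1 day holds the dye fixed.

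Per the file headers, the deposited intensity tables were Agilent Feature Extraction output of 1 channel per sample, with a processed signal, a median spot signal, a median local background and 0-or-1 flags for each of the 175906 spots that are not controls. The settings of the background subtraction and dye normalization behind the processed signal were not given in the sources used here. The deposited value table held log2 values on a scale that the sources used here did not state. Set against the processed signal, each of its columns had a slope of 1, 100% of its values lay within 0.01 of the spot-averaged log2 processed signal minus the 75th percentile of the channel, and its direction was that of the signal. The column medians of this table were -3.03, -2.94 and -2.96 for the untreated samples, -3.04, -2.96 and -2.98 for the 1-day samples, and -2.96, -2.91 and -2.89 for the 3-day samples.

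The processed signals of unflagged spots of one probe were averaged on the log2 scale, which gave 75149 probes, and the 75th percentile of the channel was subtracted. Control spots were left out. A probe was tested when it was well above background, by the flag in the files, in all 3 samples of at least 1 group, which left 47489 probes. Linear models were fitted to all 9 samples with limma 3.58.1 in R 4.3.3, with the array as a random block (duplicateCorrelation, consensus correlation 0.17) and eBayes with an intensity trend. P-values were adjusted by Benjamini-Hochberg over all tested probes, and a probe counted as changed with an adjusted p under 0.05 and a change of at least 2-fold. A probe not well above background in any sample of a group has only a bound there. For such probes the mean of the brighter group was set against the mean, per array, of the higher of the probe's own signal and the lowest signal among probes well above background.

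The files paired no probe with a gene, and no table of the array's probes was given, so each probe was a feature of its own. The gene lists and genes fixed before the data were examined could not be looked up, no count could be split into coding and noncoding genes, and the alternative that averages the probes of a gene was not run. In place of the fixed rule for named genes, the text names per comparison the probes with the 2 largest rises and the 2 largest falls among changed probes that were well above background in every sample of both groups and whose values did not overlap between them. RNA classes were taken from the probe names after the files were seen and before their values were read. They were transfer RNA (tRNA), small nucleolar and Cajal body RNA (snoRNA and scaRNA), small nuclear RNA (snRNA), ribosomal RNA (rRNA), and 3 classes whose names the files do not explain: imsncRNA, RNS, and probes named by an RNA number alone. Class shifts were tested with cameraPR, with a preset correlation of 0.01, adjusted over the 7 classes of a comparison, and again with an estimated correlation. From each class the text may name the probes with the largest changes.

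The alternatives fixed beforehand were quantile, cyclic loess and median scaling, the deposited value table, other filters on dim probes, other blocks (none, replicate number, slide), fits of the first slide alone or of only the groups compared, other thresholds (no minimum fold, or limma's treat at 1.5-fold), no intensity trend, and leaving out each sample in turn. The planned normexp correction needed a mean signal; it was run on the median spot signal instead, with an offset of 50, as an alternative chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 from tables made with pandas 2.3.3.

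The fit was tested on simulated data for all 47489 probes, of which 50 were changed by each fold named below. That is a far smaller part than was called in the real data, so the detection shares need not carry over. In the comparison of 1 day with untreated samples, 2% of probes changed by 1.5-fold, which is under the minimum fold, 84% of those changed by 2.83-fold, 100% of those changed by 4-fold and 98% of those changed by 8-fold were called in the right direction, and 2 unchanged probes were called. In that of 3 days with untreated samples the shares were 0%, 78%, 100% and 94%. The simulated spread of a probe was the same in every group. In the real data the median SD was 0.21 (log2) at 3 days and 0.13 in each of the other groups. The simulation therefore does not show how often unchanged probes are called in comparisons with the 3-day samples. The number of arrays limits the precision.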

Results

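RNA levels were measured on arrays in MSCs derived from H1 human embryonic stem cells, stromal cells of the kind studied for their effects on immune cells, without treatment and after 1 day or 3 days of IFN-γ, with 3 samples in each group. The design asks how the transcriptome of these cells changes with IFN-γ and whether the change differs between the times. Between 63.2% and 66.1% of the 75149 probes were well above background in the untreated samples, between 60.6% and 63.9% in the 1-day samples and between 54.9% and 60.01% in the 3-day samples. The 75th percentile of the processed signal ran from 254 to 392 over the 9 samples, and the median signal of the negative controls from 2.89 to 5.73. Samples of one group correlated across probes with r from 0.994 to 0.995 (untreated), from 0.992 to 0.995 (1 day) and from 0.979 to 0.987 (3 days). Untreated and 1-day samples correlated with r from 0.954 to 0.961, and untreated and 3-day samples with r from 0.938 to 0.952. The 1-day and 3-day samples, which share a dye, correlated with r from 0.969 to 0.984, which overlaps the range within the 3-day group. The first principal component, with 60.1% of the variance, parted the untreated samples from both treated groups, which is also the split between the dyes, and along the second, with 19.7%, the 3-day sample of the first slide (3.46) lay between the 1-day samples (-59.0 to -51.7) and the other 3-day samples (60.1 and 68.9). The median SD of a probe between replicates was 0.13 (log2) in the untreated and in the 1-day samples and 0.21 in the 3-day samples, which alone lay on 3 slides.

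The first comparison asks what 1 day of IFN-γ changed. Of the 47489 probes tested, 2515 were higher and 2485 lower than in untreated cells (limma, adjusted p under 0.05, at least 2-fold). The large changes counted were mostly rises, but the background limits how large a fall can show. At 16-fold or more, 143 probes were higher and 9 lower, and at 64-fold or more 22 were higher and 1 lower. In these counts 600 probes called lower and 406 called higher had only a bound, with medians of 2.71-fold and 3.23-fold. The counts therefore do not compare the sizes of rises and falls evenly. The probe A_33_P3301331 rose from -3.25 ± 0.28 to 3.92 ± 0.06 (log2 signal relative to the 75th percentile, mean ± SD, n = 3), a 144-fold change (log2 change 7.17, SE 0.13, limma adjusted p = 1.9e-13). A_32_P87697 rose 142-fold (log2 change 7.15, SE 0.11, limma adjusted p = 7.9e-14). The strongest falls were those of A_23_P106194, from 2.61 ± 0.08 to -3.40 ± 0.14, which was 64.3-fold lower (limma adjusted p = 1.1e-11), and of A_23_P429998, which was 24.3-fold lower (limma adjusted p = 2.0e-12). These 4 probes changed the same way in all 3 treated samples, which their selection for values that do not overlap required. Another 427 probes were well above background in all 1-day samples and in no untreated sample, of which 388 passed the test as higher, and 896 were the reverse, of which 598 passed as lower. Among changed probes dim in one group, the largest rise was at least 64.3-fold and the largest fall at least 23.3-fold. The untreated samples carried Cy3 and the 1-day samples Cy5. With normexp on the median spot signal, 983 probes were higher and 621 lower. This alternative changes the signal and the background correction, leaves out the dye normalization and adds an offset of 50. The median processed signals were 34.2 to 50.4, so an offset of this size shrinks log2 changes of dim probes by construction. The lower counts therefore cannot be read as the part due to dye. With normexp the log2 changes of these 4 probes were 5.41 for A_33_P3301331, 5.79 for A_32_P87697, -4.26 for A_23_P106194 and -4.32 for A_23_P429998.

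**Figure D1:**
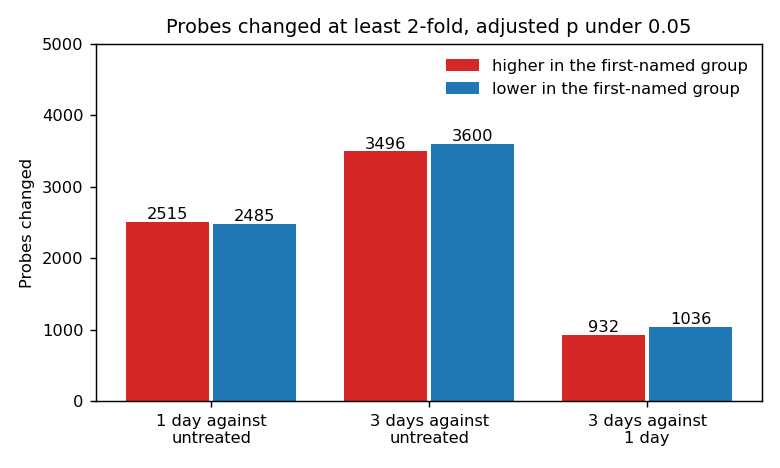
Number of probes changed at least 2-fold at an adjusted p under 0.05 (vertical axis) in each of the 3 comparisons (horizontal axis), with red bars for probes higher and blue bars for probes lower in the first-named group. Both comparisons with untreated cells changed more probes (2515 and 2485, 3496 and 3600) than the comparison of 3 days with 1 day (932 and 1036).

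The second comparison asks what 3 days of IFN-γ changed. Against untreated cells, 3496 probes were higher and 3600 lower. At 16-fold or more, 160 were higher and 11 lower, and the background limits the size of falls here too. Only a bound was available for 1046 probes called lower and 374 called higher, with medians of 2.10-fold and 3.48-fold. A_32_P87697 showed the largest rise among probes measured in every sample of both groups, from -2.61 ± 0.22 to 5.85 ± 0.11 (log2, mean ± SD, n = 3), which was 353-fold (log2 change 8.46, SE 0.12, limma adjusted p = 6.4e-14). A_23_P45099 rose 301-fold (log2 change 8.23, SE 0.13, limma adjusted p = 8.6e-14). A_23_P204286 was 66.6-fold lower, at 2.91 ± 0.42 untreated and -3.14 ± 0.21 at 3 days (limma adjusted p = 3.0e-11). A_23_P106194 was 31.96-fold lower (limma adjusted p = 2.4e-10). Among changed probes dim in one group, the largest rise was at least 552-fold and the largest fall at least 21.8-fold. Here 227 probes were well above background in all 3-day samples and in no untreated sample, of which 225 passed the test as higher, and 2351 were the reverse, of which 1038 passed as lower. Of 1046 probes called lower that were dim in all 3-day samples, 593 had a bound of at least 2-fold. The lowest signal well above background was higher in the 3-day samples (-4.84, -5.01 and -4.40, log2) than in the untreated samples (-5.47, -5.60 and -5.67). The dyes differed here too. With normexp on the median spot signal and its offset of 50, 1101 probes were higher and 844 lower. The log2 changes were then 7.04 for A_32_P87697, 5.06 for A_23_P45099, -4.27 for A_23_P204286 and -3.72 for A_23_P106194. With slide as a fixed term 3187 were higher and 3533 lower, and on the first slide alone, which held a single 3-day sample, 3179 and 3546.

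The third comparison, of 3 days with 1 day, holds the dye fixed and asks whether the response went on changing. At 3 days, 932 probes were higher and 1036 lower than at 1 day. These changes were smaller, with 65 higher and 106 lower at 4-fold or more, and 2 higher and 0 lower at 16-fold or more by limma (without a minimum fold, 5753 were higher and 5566 lower). A_33_P3293049 rose from -0.10 ± 0.26 to 3.56 ± 0.08 (log2, mean ± SD, n = 3), which was 12.6-fold (SE of the log2 change 0.25, limma adjusted p = 2.1e-06). It was not well above background in any untreated sample. A_33_P3273884 rose 12.1-fold (limma adjusted p = 2.9e-07). A_23_P207456 was 9.52-fold lower at 3 days than at 1 day (limma adjusted p = 1.4e-07). Its levels were -3.11 ± 0.08 untreated, 1.58 ± 0.07 at 1 day and -1.67 ± 0.33 at 3 days, so that it remained above untreated at 3 days (log2 change 1.44, limma adjusted p = 1.1e-05). The probe p23681 was 6.39-fold lower at 3 days than at 1 day (limma adjusted p = 0.0011), with an SD of 1.09 (log2) between the 3-day samples, and it did not pass with normexp (log2 change -0.995). The log2 changes of A_33_P3293049, A_33_P3273884 and A_23_P207456 with normexp were 3.29, 3.34 and -2.44. Here 42 probes were well above background in all 3-day samples and in no 1-day sample, of which 41 passed as higher. The reverse held for 920, of which 212 passed as lower. Of 257 probes called lower with only a bound at 3 days, 117 had a bound of at least 2-fold. This comparison depended most on single samples and on slide. On the first slide alone 691 probes were higher and 874 lower, and 956 of the 1968 changed probes were called the same way. Without the 3-day sample of the first slide the counts were 1541 and 1786, and without the first 1-day sample 741 and 651. With median scaling, 718 were higher and 1323 lower, which is 35.2% against 47.4% higher.

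Most probes higher at 1 day were also higher at 3 days. Of the 2515 probes higher and the 2485 lower at 1 day, 1930 and 1585 changed the same way at 3 days, against 185 and 188 for independent lists of these sizes, and 4 and 7 changed the opposite way. Both comparisons share the untreated samples. Across probes, which are not independent replicates, the log2 changes correlated with r = 0.81 against 0.50 for simulated unchanged groups sharing their controls. The covariance was 0.50 against 0.020, a difference of 0.48. With 3 untreated samples the controls could not be split, so part of the excess may come from them. Both comparisons also share the difference between Cy5 and Cy3, which the simulation leaves out and which the design does not separate from a lasting response. With regard to time, 1747 probes were higher at both times with no call between them, and 107 were higher at 1 day and higher still at 3 days. Another 76 were higher at both times but lower at 3 days than at 1 day, 110 were higher at 1 day alone and lower at 3 days than at 1 day, and 348 were higher at 3 days than in both other groups with no call at 1 day. Of falling probes, 1487 were lower at both times with no call between them, 52 were lower still at 3 days, 46 had come partly back, 185 were lower at 1 day alone and higher at 3 days than at 1 day, and 590 were lower at 3 days than in both other groups with no call at 1 day. These 590 hold 66 of 68 probes that were well above background in all samples of the first slide and in none of the other slides, at least 2 (log2) apart. Another 4254 probes had other combinations of calls, such as a call against untreated at 3 days alone with none between the times. The 348 and 590 are therefore not all probes called against untreated at 3 days alone.

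**Figure D2:**
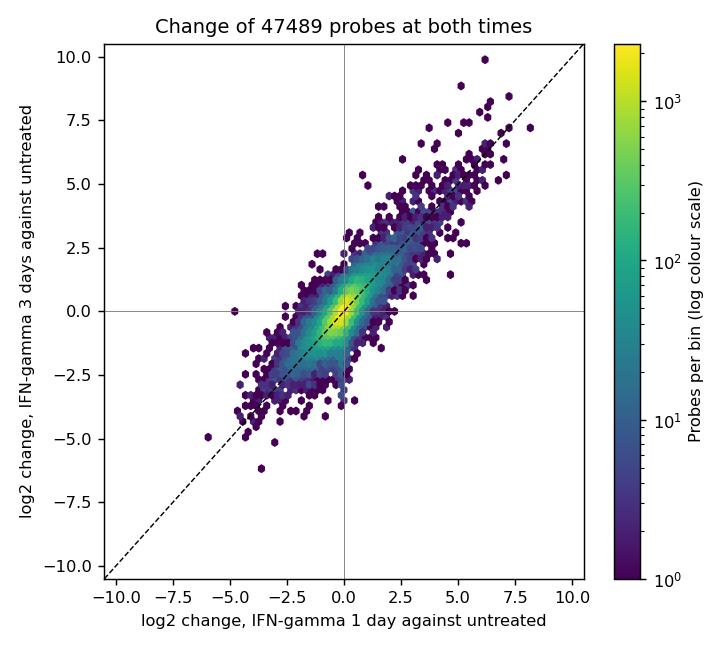
Log2 change of the 47489 tested probes at 1 day (horizontal axis) and at 3 days (vertical axis), each against untreated, with colour giving the number of probes per bin on a log scale and the dashed line marking equal change. Most large changes lie near that line (r = 0.81 across probes), and the untreated samples are shared.

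The probe names gave the class of some small RNAs. The tRNA probes, which measure the RNAs that carry amino acids to the ribosome, were bright, and their change after IFN-γ was more negative than that of the other probes. At 1 day the median log2 change of the 82 tested was -0.64, and 81.7% of them had a negative change, although 9 passed the threshold as higher and 1 as lower (cameraPR adjusted p = 1.6e-05; adjusted p = 0.90 with an estimated correlation). At 3 days the median was -0.85, with 3 higher and 31 lower (cameraPR adjusted p = 9.1e-09; adjusted p = 0.43 with an estimated correlation), and on the first slide alone it was -0.82. The mean over samples of the class median was 4.49 ± 0.06 untreated, 3.67 ± 0.09 at 1 day and 3.56 ± 0.27 at 3 days (log2, SD, n = 3). The probe tRNA_459_68 was 2.66-fold lower at 3 days (log2 change -1.41, SE 0.14, limma adjusted p = 4.5e-06), and tRNA_374_71 was 2.96-fold higher at 1 day (limma adjusted p = 3.8e-07). Near-identical tRNA copies can share signal, so single tRNA probes are uncertain. Between 3 days and 1 day the tRNA median was -0.14 (cameraPR adjusted p = 0.0041; adjusted p = 0.63 with an estimated correlation), and 0 were higher and 1 lower. It was -0.07 on the first slide alone. Without the third 3-day sample it was -0.03 and did not pass; the class median of that sample was 3.24, while those of the other 3-day samples, 3.72 and 3.71, lay within the 1-day range of 3.57 to 3.74.

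The snoRNA and scaRNA probes, whose RNAs guide the modification of ribosomal and spliceosomal RNA, also had a negative median change after IFN-γ. Of 267 tested, 3 were higher and 30 lower at 1 day (median log2 change -0.30, cameraPR adjusted p = 5.8e-04; adjusted p = 0.90 with an estimated correlation), and 5 were higher and 27 lower at 3 days (median -0.30, cameraPR adjusted p = 0.020; adjusted p = 0.43 with an estimated correlation; -0.26 on the first slide alone). Without the 3-day sample of the first slide the 3-day shift no longer passed (median -0.27). The probe snoRNA_scaRNA_326_71 was lower at both times, 5.41-fold at 1 day (log2 change -2.44, SE 0.16, limma adjusted p = 5.9e-08) and 5.23-fold at 3 days (limma adjusted p = 2.3e-07). Between 3 days and 1 day their median was 0.07 (cameraPR adjusted p = 0.16). The 78 snRNA probes, for RNAs of the spliceosome, showed no class shift at 1 day (median -0.06, mean 0.08, cameraPR adjusted p = 0.79), at 3 days (median -0.02, mean 0.03, adjusted p = 0.68) or between the times (median 0.05, mean -0.05, adjusted p = 0.96). Of these, 5 were higher and 1 lower at 1 day, and 8 higher and 9 lower at 3 days.

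**Figure D3:**
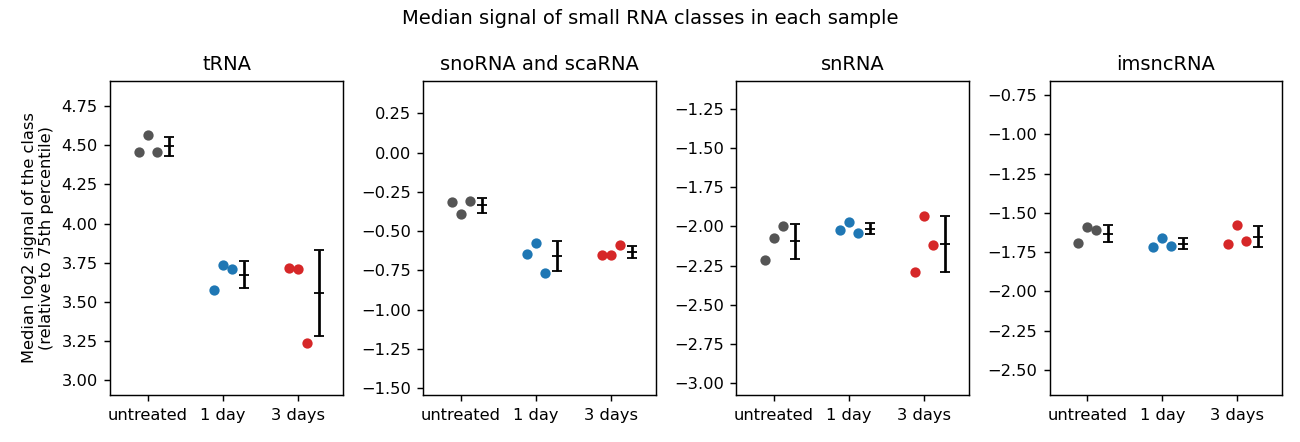
Median log2 signal of each class relative to the 75th percentile (vertical axes, each spanning the same log2 range) in the 3 samples of each group (points), with mean and SD over samples (black bar). The tRNA medians lie at 4.49 ± 0.06 untreated and at 3.67 ± 0.09 and 3.56 ± 0.27 after 1 and 3 days, while the imsncRNA medians stay between -1.72 and -1.58.

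Of the 705 imsncRNA probes, 12 were higher and 39 lower at 1 day and 29 higher and 46 lower at 3 days, with class medians of -0.03 and 0.02 (cameraPR adjusted p = 0.79 and 0.96). One of them, the probe p0249_imsncRNA392, rose 73.3-fold at 1 day (log2 change 6.20, SE 0.19, limma adjusted p = 3.3e-11) and stood 29.1-fold above untreated at 3 days (limma adjusted p = 1.4e-09). Of the 861 RNS probes, 15 were higher and 19 lower at 1 day, and 39 higher and 35 lower at 3 days. RNS_753_129 rose 40.6-fold at 1 day (log2 change 5.34, SE 0.13, limma adjusted p = 3.2e-12) and was 24.8-fold above untreated at 3 days. The RNS class median between 3 days and 1 day was 0.14 (cameraPR adjusted p = 0.043; adjusted p = 0.63 with an estimated correlation), and the shift did not pass on the first slide alone (0.13) or under 9 other alternatives. The 11 rRNA probes had a median of 0.32 in that comparison (cameraPR adjusted p = 0.043; adjusted p = 0.24 with an estimated correlation), 0.42 on the first slide alone, and 1 of them was higher. This shift did not pass under 8 of 27 alternatives, and its median was 0.20 without the third 3-day sample and 0.21 without the first 1-day sample. Over all alternatives the median ran from 0.10 to 0.50. Their median at 1 day was 0.20 while their mean was -0.06 (cameraPR adjusted p = 0.87). The 15 probes named by an RNA number alone had a median of 0.80 at 3 days against untreated (cameraPR adjusted p = 6.5e-04; adjusted p = 0.43 with an estimated correlation) and of 0.61 against 1 day (cameraPR adjusted p = 1.1e-06; adjusted p = 0.24 with an estimated correlation). Of these probes, 3 were higher than untreated and 1 higher than at 1 day. The class median stood at 6.05 and 5.88 in the first and second 3-day samples and at 4.89 in the third, which lies within the untreated range of 4.61 to 5.09.

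Control spots carried the only names of human genes in the files, GAPDH and PGK1, both enzymes of glycolysis. GAPDH spots for the 3' part of the transcript stood at 6.45 ± 0.19 untreated, 6.78 ± 0.04 at 1 day and 6.85 ± 0.10 at 3 days (log2, mean ± SD, n = 3). Those for the 5' part stood at 6.01 ± 0.14, 6.09 ± 0.03 and 6.33 ± 0.23. PGK1 spots for the 3' part stood at 4.96 ± 0.08, 5.57 ± 0.07 and 4.90 ± 0.04, and those for the 5' part at 2.33 ± 0.04, 3.47 ± 0.14 and 2.92 ± 0.36. For control spots too, untreated against treated is Cy3 against Cy5. Of the control spots named E1A_r60, which measure no human gene, some differed between the groups by more and others by less. Those ending in a20 changed by -0.04 at 1 day and 0.15 at 3 days. Those ending in n9 stood at 0.39 ± 0.12, 2.92 ± 0.27 and 3.73 ± 0.41, and those ending in r60_3 at -0.35 ± 0.26, -2.31 ± 0.30 and -1.50 ± 0.47. With 3 samples against 3, an exact two-sided permutation test cannot go below p = 0.1.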

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

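Of the tests in this part, those of dye, of constant material and of slide on the changes between 3 days and 1 day were chosen after the result was seen; those of signal, of slide sensitivity and of other splits were fixed before it. Some control spots, which no comparison of probes uses, differed from the untreated level. These differences are also between Cy5 and Cy3, so they cannot be credited to IFN-γ. Whether the material measured by the E1A_r60 spots was added in equal amounts with both dyes was not tested. The differences of these spots, which went both ways, therefore do not measure dye bias either. The E1A_r60_n9 spots stood 2.54 (log2) above untreated at 1 day and 3.35 above at 3 days, and the E1A_r60_a107 and E1A_r60_a135 spots 1.76 and 1.39 above at 3 days, while the E1A_r60_3 and E1A_r60_a104 spots stood at -1.96 and -1.75 relative to untreated at 1 day. The human PGK1 spots for the 5' part stood 1.14 (log2) above untreated at 1 day, and the mouse and rat versions of that spot 1.24 and 1.23 above. The rat GAPDH spots for the 5' part stood 1.28 above untreated at 3 days. In addition, 11 probes changed in opposite directions at 1 day and at 3 days against untreated and also differed between the times in limma's test of that difference, and 9 of them did so on the first slide alone, with its single 3-day sample.

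The first pattern is the number of probes changed against untreated, a comparison that is also one of Cy5 with Cy3. Of the probes changed at 1 day, 11.7% also differed between 3 days and 1 day, which share a dye, against 3.25% of the other probes. This does not exclude dye, since both calls use the same 1-day samples, the 3-day samples lie partly on other slides, and 1-day samples share their arrays with untreated samples while 3-day samples do not. For these probes and for the remaining 4413 probes changed at 1 day, dye and treatment cannot be told apart, because no dye was swapped. Regrouping the samples cannot give a share under 0.05, since 3 samples against 3 allow 10 splits. The fits used those samples alone, were run without the array block and went over splits that ignore shared arrays. The real split gave 5015 changed probes at 1 day, 6994 at 3 days and 1550 between the times, the largest in 1 of the 10 splits each time. The highest of the others gave 0, 0 and 0. Every other split mixes the groups, so a difference between them, whatever its cause, adds to the spread within the split. The counts of 0 are therefore not a rate of calls by chance.

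The second pattern is the lower signal of tRNA and of snoRNA and scaRNA probes. Among 10000 lists of probes matched on mean signal, the 1-day medians of both classes lay at percentile 0, against matched ranges from -0.11 to 0.07 and from -0.08 to 0.04. The lists drew probes singly, while probes of a class varied together (estimated correlation 0.42 and 0.09), so these ranges are too narrow. A shift shared by probes of like signal is argued against only if class members vary independently. The set test with an estimated correlation gave adjusted p = 0.90 for both classes at 1 day. Dye stays open for both classes. The shift between 3 days and 1 day, which share a dye, had an adjusted p of 0.63 with an estimated correlation for either class. A class effect of IFN-γ on these RNAs is the biological alternative, and the design cannot separate it from a different dye response of short, structured RNAs.

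The third pattern is slide. There were 68 probes well above background in all 7 samples of the first slide and in neither sample of the other slides, at least 2 (log2) apart, and 0 the reverse. Other pairs of samples of one group gave at most 1 such probe. Probes of like signal differed between the slides by a median of -0.045 against 3.25 for this set, which was selected for a gap of at least 2. Scaling to the 75th percentile removes a loss of signal shared by all probes, so such a loss was not tested here. The values argue only against a further loss on the other slides shared by probes of like signal. Over the 7 first-slide samples, across 2 dyes and 3 treatments, the median SD of the set was 0.17. It lay at percentile 0 of 10000 lists of probes of like signal that pass the same thresholds on the first slide (median 0.25, lowest 0.19), which is consistent with material added at a constant amount to that slide's hybridizations, as a hypothesis; a difference between cultures stays open. For the changes between 3 days and 1 day at large, 3084 to 3484 probes were called from the 3-day samples of the other slides. Of these, 74.9% to 77.7% went the same way in the 3-day sample of the first slide, with a median of 0.37 to 0.48. The shares were 78.3% to 88.8% of the rises and 64.7% to 73.5% of the falls. Holding out either other 3-day sample gave 94.7% of 1523 and 93.5% of 1581 probes, with a median of 1.06 to 1.08. Those probes were called from the first slide and another slide together, which selects for agreement across slides, so the shares are not alike. With a single 3-day sample on the first slide, slide and culture cannot be told apart.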

How the results depend on the processing

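The normexp, floor and slide-set alternatives were chosen after seeing the data; the others were fixed beforehand. Of 189 recomputed counts, 162 stayed within 1.5 times the main value and 27 did not. The cause was not tested unless named. Requiring no minimum fold gave 8320 higher and 10301 lower probes at 1 day, 10936 and 12252 at 3 days, 5753 and 5566 between the times, and 13326 shared by both comparisons with untreated; this threshold is looser by construction. Normexp on the median spot signal without dye normalization changes several choices together, and its offset of 50 shrinks changes of dim probes by construction. It gave 983 and 621, 1101 and 844, 154 and 196, and 1085 shared. Testing only probes well above background in all 9 samples, which leaves fewer probes, gave 1278 lower at 1 day, 1776 lower at 3 days, 582 higher and 423 lower between the times, and 2042 shared. With no filter on dim probes, 6503 were higher at 3 days against untreated and 2175 against 1 day, and the median of all probes moved to 0.21 and 0.19. The treat test at 1.5-fold called 2307 lower at 3 days and 246 higher and 192 lower between the times. Leaving out each sample in turn gave 2432 to 2553 higher and 2373 to 2586 lower at 1 day, 3276 to 4036 and 3306 to 4123 at 3 days, 741 to 1541 and 651 to 1786 between the times, and 3415 to 3560 shared; on the last comparison, leaving out the first 3-day sample gave the highest counts and the first 1-day sample the lowest. The share of higher calls between the times was 47.4%, and 35.2% with median scaling, 64.6% with no filter (2175 higher, 1192 lower) and 57.9% for probes well above background in all samples; with no filter it moved from 49.3% to 62.5% at 3 days (6503 higher, 3909 lower). With values floored at the lowest signal well above background, 3470 were higher and 3071 lower at 3 days, and 924 and 857 between the times. Without the 68 slide-linked probes 3532 were lower at 3 days and 967 lower than at 1 day.

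Deviations of same-numbered untreated and 1-day samples, which share an array, correlated with r = 0.22, 0.21 and 0.04, so they did not all pass 0.1 and the replicate number was not a fixed block in the main fit, although each untreated sample correlated best with its own number. The array, as a random block, already ties these samples in that fit. With the replicate number as a block, 2497 and 2460 probes changed at 1 day, 3493 and 3584 at 3 days and 936 and 1021 between the times, and 4952 of 5000, 7063 of 7096 and 1918 of 1968 changed probes were called the same way. Slide as a random block gave 728 and 742 between the times, and as a fixed term 702 and 866.

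No class median or named probe changed sign while called. Of 567 recomputed class medians, 546 kept their side of the threshold, 20 no longer passed and 1 newly passed. Those lost were the rRNA shift between the times under 8 alternatives and the RNS shift under 10, the tRNA shift between the times without the third 3-day sample (-0.03), and the snoRNA and scaRNA shift at 3 days without the first 3-day sample. Of 321 recomputed changes of named probes, 320 kept theirs, and p23681 no longer passed with normexp (-0.995). The tRNA median ran from -0.71 to -0.47 at 1 day and from -0.98 to -0.60 at 3 days over all alternatives. The snoRNA and scaRNA median ran from -0.34 to -0.21 at 1 day and from -0.35 to -0.11 at 3 days. Signal over background limits the 3-day samples most, in which 54.9% to 60.01% of probes were well above background. The planned normexp on mean signal and the mean of probes per gene were not run, for want of a mean signal and of gene names.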

Other observations

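The test of probe numbers below was chosen after the result was seen. Several imsncRNA probes carry the same number, which the files do not explain. A candidate explanation is that a number names one RNA measured by several probes. Across 81 pairs among 113 probes of 50 numbers, log2 changes at 1 day correlated with Pearson r = 0.77 and Spearman rho = 0.70 (permutation p = 1e-04, the smallest that 10000 shuffles can give, adjusted p = 1e-04 over 3 comparisons). The highest shuffled r was 0.52, and r was 0.71 without the 2 most extreme pairs. For 3 days against 1 day, which share a dye, r was 0.58 and rho 0.50 (permutation p = 1e-04, again the smallest), and r was 0.49 without the 2 most extreme pairs. Probes and pairs are not independent replicates, and one probe can stand in several pairs.

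Of the external RNA control (ERCC) spots, 2 were bright in all groups while most others were near the background. ERCC-00012_90 stood at -0.68 ± 0.07, -0.52 ± 0.10 and -1.12 ± 0.72 (log2, mean ± SD, n = 3) in the untreated, 1-day and 3-day samples, and ERCC-00043_129 at -1.71 ± 0.13, -1.32 ± 0.11 and -1.52 ± 0.34, while ERCC-00053_71 stood at -6.59 ± 0.11, -6.48 ± 0.16 and -5.79 ± 0.33. Control spots differed in both directions between the 3-day sample of the first slide and those of the other slides. E1A_r60_a22 stood at 3.12 against 1.45 and 0.77, DCP_22_0 at 3.13 against 1.38 and 0.81, and ERCC-00012_90 at -0.38 against -1.16 and -1.82, and the other DCP_22 spots were also brightest on the first slide. E1A_r60_1 stood at -0.72 against 0.05 and 0.46, E1A_r60_n9 at 3.27 against 3.87 and 4.06, and DCP_1_0 at -0.64 against 0.11 and 0.53, and the other DCP_1 spots were also dimmest on the first slide. The levels of DCP_22_0 were close to those of E1A_r60_a22, and the levels of DCP_1_0 to those of E1A_r60_1. Whether such spots measure separate material was not tested, so they cannot be counted as separate controls.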
